A study of Homo sapiens with 8 samples.

How the data were processed

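The data were ChIP-seq peak summits of phosphorylated B-MYB from LNCaP cells, with 2 libraries treated with 1 nM R1881 and 2 with DMSO. Per the labels' protocols, cells were fixed with 1% formaldehyde, sonicated and immunoprecipitated with 5 ug of the antibody, and libraries were read as 50 bp single ends on a HiSeq2000. The input libraries, which received no antibody, were not analysed here.

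Reads were aligned with Bowtie2 and peaks were called with MACS2, per the submitters' processing notes, which give no versions. Whether the inputs served as controls, how duplicate reads were treated and how reads with several matches in the genome were placed are not given in the sources used here. The authors called peaks separately in each library and deposited 1 list per library, with the position of each summit, 1 bp long, and a score. The deposited score is the −log10 of a p-value or q-value as the peak caller writes it, and which of these it is was not given. The lowest scores, 1.32 to 1.68 over the 4 lists, lie just above 1.301, the −log10 of 0.05, and the peak names are numbered without a gap, so no peak is missing from within a list. A score depends on read depth, which is unknown, and was used only to rank or filter summits within a list. A deeper library yields more peaks at a fixed threshold, so the numbers of summits of these lists cannot be scaled to equal depth.

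The submitters' processing notes name hg38 as the genome build, but the deposited positions are those of hg19. Contig names are of the hg19 form, and on chromosomes 4, 8, 9, 10, 21 and Y the last summit lies beyond the last feature annotated in GRCh38, on chromosome Y at 58997119 against 57214397. The only reference at hand was a GRCh38 annotation, and positions were not converted between builds. For this reason 5 planned results were not run: the share of summits at promoters, the MYB motif at R1881 and at DMSO sites, and the fixed gene lists near R1881 and near DMSO sites. The gene lists and motifs fixed for them were therefore not tested.

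Groups and replicate numbers came from the labels. Positions are given 1-based. Counts and sites used chromosomes 1 to 22, X and Y, and the accounts of windows and regional shares used all sequences. Summits of the 4 libraries were joined into sites by single linkage at 250 bp, and a site belonged to each library with a summit in it. For a comparison of just 2 libraries, sites were built from those libraries alone. The longest site spanned 644 bp. A crowded window was a 100 kb bin with at least 5 summits over the 4 libraries, and 108 such bins held 3558 summits (89.6%). Bins are fixed, so a site just outside a crowded bin, such as the one at chromosome 16 46392049, counts as outside. Shares were compared in 1 Mb windows with at least 20 summits and on 26 chromosomes and contigs.

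Numbers of summits were compared by an exact two-sided permutation test of library labels. Shares were compared within each replicate number by Fisher's exact test with Benjamini-Hochberg adjustment over 52 tests, with 95% Wilson intervals. Sharing of sites was compared, one-sided, with 100000 random placements of 1 library within the span of each chromosome up to its last summit, and with 10000 draws in which each summit of 1 library was moved by 500 to 5000 bp. Sites exclusive to each of the 6 pairs of libraries were counted without a test. The named sites were the 10 with the best mean rank of score within their lists among those of both R1881 libraries alone, both DMSO libraries alone and all 4 libraries, and the highest-scoring site of each library. This rule, the comparisons and most alternatives were fixed before the data were examined. The comparison with moved summits, the windows and regional shares, the counts by kind of pair, and the clusters and lone sites outside the rule were added after seeing the data.

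The overlap step was tested on simulated data made from R1881 replicate 1, with 600 summits and 5 simulated pairs of lists per kind. The number of shared sites found was on average 100% of the number planted, without following single summits. The other summits of these lists were placed at random along chromosomes, unlike the crowded real lists. Pairs of lists that shared regions but no planted sites were called in 5 of 5 cases against random placement, so random placement does not separate shared sites from shared regions. They were called in 0 of 5 against moved summits. These lists were themselves made by moving each summit over similar distances, so that result was nearly fixed in advance. It does not show how the comparison with moved summits behaves on real lists. Alternatives were a minimum score of 5, lists of equal length (the 600 highest-scoring summits of each library on chromosomes 1 to 22, X and Y, or the 651 highest-scoring where all sequences were used), all sequences, crowded windows left out, joining distances of 100 and 1000 bp, each library left out in turn, and the replicate number as a block. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and plots matplotlib 3.10.9.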

Results

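LNCaP is a human prostate cancer cell line that carries the androgen receptor and responds to androgen. The cells were held in medium with charcoal-treated serum, which is low in steroids, and then received 1 nM R1881, a synthetic androgen, or only its solvent, DMSO. The design text of the series gives 12 h of treatment, while the protocol lists 6, 12 or 24 h. Chromatin was immunoprecipitated with an antibody against B-MYB, a transcription factor of the cell cycle, phosphorylated at threonine 487, and the recovered DNA was sequenced (ChIP-seq), to find where this form of B-MYB lies on the genome with and without androgen. Each treatment had 2 ChIP libraries, replicates 1 and 2. The 4 input libraries, made without antibody, were not analysed here. Each ChIP library had its own list of peak summits, the single base at which a peak was highest, with 651 summits in R1881 replicate 1, 1779 in R1881 replicate 2, 1242 in DMSO replicate 1 and 1214 in DMSO replicate 2. The read depth behind these lists is unknown, because they hold no read counts. The names of the peaks within the list of DMSO replicate 2 carry a 0 h tag where the labels say DMSO, and the library was kept in the group its labels give. Positions are hg19 coordinates throughout, and no annotation of that build was used here, so sites are given by position without gene names.

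The first question was where on the genome the summits lay. In both treatments they crowded into a few regions, many of them in sequence known to lie beside centromeres. The fullest 1 Mb window, chromosome Y 13 to 14 Mb, beside the centromere, held 93 and 193 summits in R1881 replicates 1 and 2 and 107 and 173 in DMSO replicates 1 and 2. Chromosome 21 10 to 11 Mb, also near a centromere, held 38 and 122 summits in the R1881 libraries and 62 and 92 in the DMSO libraries. On both sides of the centromere of chromosome 10, the window at 39 to 40 Mb held 36, 75, 35 and 80 summits and the window at 42 to 43 Mb held 39, 68, 75 and 55, in the order R1881 replicates 1 and 2 and DMSO replicates 1 and 2. The unplaced contig gl000216 held 45, 86, 54 and 83 summits in the same order.

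The 10 fullest windows held 57.8% and 48.8% of the summits of R1881 replicates 1 and 2, and 50.4% and 62.7% of those of DMSO replicates 1 and 2. Of the 252 windows with any summit, 39 had at least 20, and these held 4160 of all 4886 summits (85.1%). All 4 libraries had summits in 22 of the 39, and 16 of the 39 had none of R1881 replicate 1. Summits on contigs without a fixed chromosome position made up 7.68% of R1881 replicate 1, against 18.7% of R1881 replicate 2, 20.2% of DMSO replicate 1 and 22.2% of DMSO replicate 2.

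**Figure D1:**
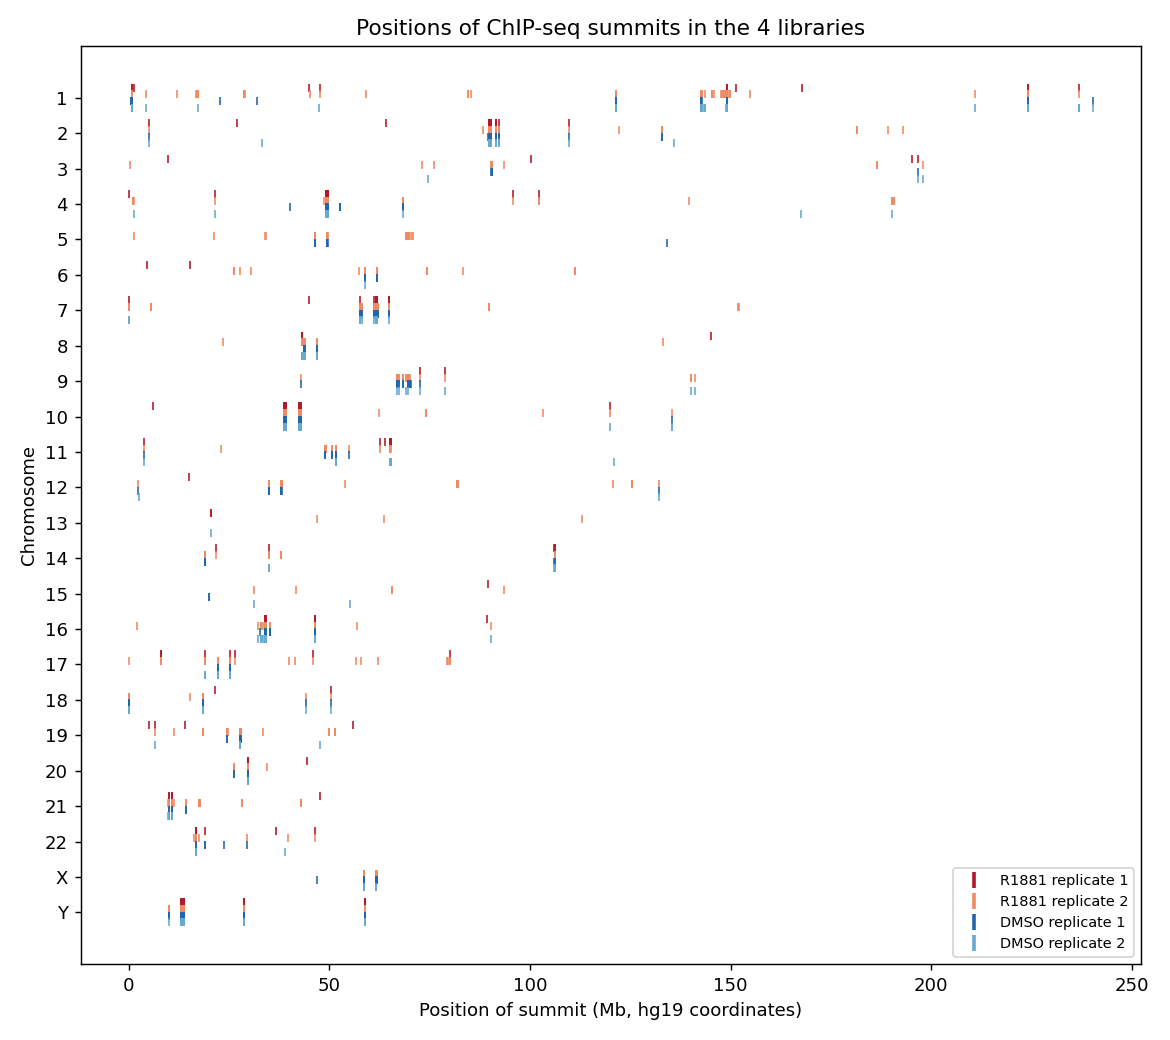
Position of every summit (x axis, Mb, hg19) on chromosomes 1 to 22, X and Y (y axis), with 1 tick per summit and 1 colour per library (reds R1881, blues DMSO). Ticks of all 4 libraries pile up at a few places such as chromosome Y 13 to 14 Mb and chromosome 10 on both sides of the centromere, while R1881 replicate 2 has the most scattered ticks.

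The next comparison was the number of summits with and without androgen. On chromosomes 1 to 22, X and Y, the R1881 libraries had 600 and 1446 summits and the DMSO libraries 982 and 944, which gives 1023 ± 598 (SD, n = 2) and 963 ± 26.9 (SD, n = 2). The log2 ratio of these means was 0.09, and an exact two-sided permutation test gave p = 1.0, where 0.333 is the smallest p that 2 against 2 libraries allow. The R1881 libraries differed from each other by 2.41-fold and the DMSO libraries by 1.04-fold, so the difference between treatments was far smaller than the spread between the R1881 replicates. Within replicate 1 the R1881 number was 0.611 times the DMSO number, and within replicate 2 it was 1.53 times. Outside the 108 crowded 100 kb windows, which held 5 or more summits each, R1881 replicate 2 stood apart with 241 summits, against 56 in R1881 replicate 1 and 58 and 59 in the DMSO libraries, and the log2 ratio there was 1.34. The labels do not say whether replicates came from separate cultures, so this permutation p of library labels measures only the spread between these libraries, which may be technical.

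Regional shares with and without androgen were compared next. Summits on chromosome Y made up a larger share with R1881 than with DMSO in replicate 1, at 23.5% (95% Wilson interval 20.4 to 26.9) against 13.6% (11.8 to 15.6), but not in replicate 2, at 15.2% (13.6 to 16.98) against 17.3% (15.3 to 19.5). Benjamini-Hochberg adjusted p-values of Fisher's exact test were 1.42e-06 and 0.24. Chromosome 10 went opposite ways, with 14.9% against 10.1% in replicate 1 (adjusted p = 0.00926, Fisher's exact test) and 11.02% against 15.3% in replicate 2 (adjusted p = 0.00261). Chromosome 4 made up 13.1% with R1881 against 6.28% with DMSO in replicate 1, and 2.64% against 1.48% in replicate 2, with adjusted p-values of 1.18e-05 and 0.0804 from the same exact test. Chromosome 5 had no summit in R1881 replicate 1 and none in DMSO replicate 2, but 33 in R1881 replicate 2 and 21 in DMSO replicate 1. The contig gl000199, assigned to chromosome 9 without a position, had a lower share with R1881 in both replicates. It was 0 of 651 summits against 10.3% in replicate 1 and 6.46% against 9.64% in replicate 2 (adjusted p = 2.3e-23 and 0.00631, Fisher's exact test). In replicate 2 the numbers of summits were nearly equal, 115 with R1881 and 117 with DMSO, on lists of 1779 and 1214. R1881 replicate 1, the shortest list, also had no summit on chromosome X.

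Over 26 chromosomes and contigs and 52 such tests, 12 passed an adjusted p of 0.05 in replicate 1 and 9 in replicate 2. Only 5 passed in both, of which 4 had opposite directions and 1, gl000199, had the same direction. Summits of a library cluster and are not replicates of a treatment, so these p-values are too small as tests of androgen, and the intervals cover counting error only. In the 39 windows with at least 20 summits, the libraries with the highest shares were a treatment pair in 4, a replicate-number pair in 10 and libraries sharing neither in 25, where chance gives each kind 33.3%. With a score of at least 5 these numbers were 7, 11 and 13 of 31 windows. With equal list lengths on chromosomes 1 to 22, X and Y the last kind made up 7 of 21, or 33.3%, the level of chance without ties. Tied windows counted there as not of this kind, and their number was not recorded. In 16 of the 39 windows R1881 replicate 1 had no summit, so it could not have a high share there. Windows of the same 4 libraries are not independent, so the level of chance is only a guide. Chromosome Y 13 to 14 Mb, a window of the kind sharing neither label, had its highest shares in R1881 replicate 1 (14.29%) and DMSO replicate 2 (14.25%), against 10.8% in R1881 replicate 2 and 8.62% in DMSO replicate 1. Other windows split by replicate number. At chromosome 4 49 to 50 Mb, shares were 12.4% in R1881 replicate 1 and 5.72% in DMSO replicate 1 but 1.52% and 1.07% in the replicate 2 libraries. Chromosome Y 58 to 59 Mb, at the end of the long arm, had 8.76% and 2.74% in replicate 1 and 1.07% and 1.07% in replicate 2.

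**Figure D2:**
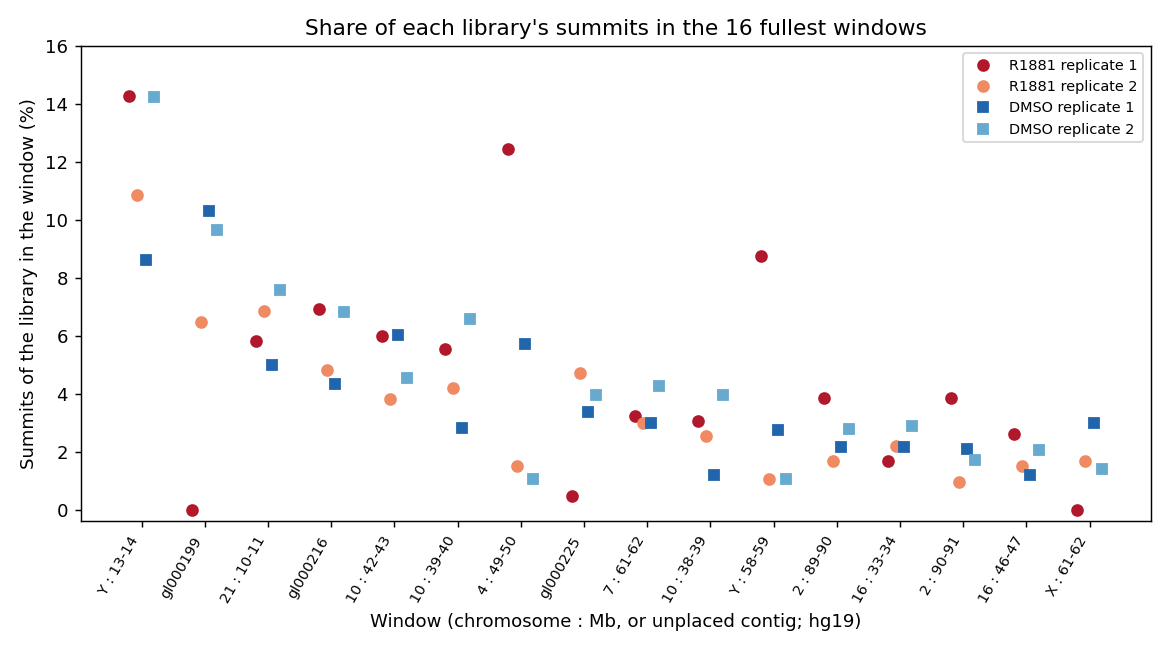
Share of each library's summits (y axis, %) in the 16 fullest 1 Mb windows or contigs (x axis, hg19), with 1 point per library, circles for R1881 and squares for DMSO. Both circles lie on the same side of both squares in 1 of the 16, contig gl000199, with 0% and 6.46% for R1881 and 10.3% and 9.64% for DMSO.

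Replicates were then compared site by site, with summits within 250 bp of the next joined into 1 site. The sites found in all 4 libraries included some of the highest-scoring of the data. One, at chromosome 16 46392049 to 46392085, had authors' scores of 99.5 and 77.1 in the R1881 libraries and 92.6 and 144 in the DMSO libraries, and was the highest-scoring site of both replicate 1 libraries on chromosomes 1 to 22, X and Y. The highest-scoring sites of the replicate 2 libraries lay in the same stretch of chromosome 16, at 46406828 for R1881, with a score of 129 and the nearest DMSO summit 3894 bp away, and at 46412999 to 46413149 for DMSO, with a score of 187. Others lay at chromosome 21 10819558 to 10819597, chromosome 20 29829545 to 29829578 and chromosome 14 106208495 to 106208511. The chromosome 4 region near the centromere gave sites at 49639636 to 49639659, 49110374 to 49110493 and 49636353 to 49636373, and chromosome 10 gave sites at 42385099 to 42385102 and 42599777 to 42599926. The scores are the authors' own values per peak and rank peaks only within 1 list.

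Of 2236 sites, 1226 (54.8%) were found in 1 library, 502 in 2, 325 in 3 and 183 (8.18%) in all 4. The R1881 replicates shared 341 sites, 57.0% of the shorter list, and the DMSO replicates shared 415, or 44.2%. Of all sites of either library the order was the reverse, 20.12% for R1881 and 27.65% for DMSO. With lists of equal length the R1881 replicates shared 251 sites and the DMSO replicates 252. For the full lists, random placement within chromosomes gave 0.549 and 0.535 shared sites on average (one-sided permutation p = 1e-05 for both, the smallest that 100000 draws can give). When each summit of 1 library was instead moved by 500 to 5000 bp, which keeps regional crowding, the averages were 119.5 and 152.9, so that sharing was 2.85 and 2.71 times that level (permutation p = 0.0001, the smallest that 10000 draws can give). Libraries of different treatments shared 313, 649, 311 and 530 sites, which were 52.69%, 69.26%, 52.09% and 54.25% of the shorter list. These numbers were 2.92, 2.71, 2.64 and 2.72 times the level after moving, so the excess within a treatment lay in the range of that between treatments. With the crowded windows left out, the R1881 replicates shared 23 sites and the DMSO replicates 14, while the replicate 2 libraries of different treatments shared 26 and the other pairs of different treatments 11, 17 and 14.

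Sites called in both libraries of a treatment and in neither of the other were few. Both R1881 libraries and neither DMSO library had a summit at 34 sites, and both DMSO libraries and neither R1881 library at 38. With a joining distance of 1000 bp these numbers were 14 and 8, and with all sequences 35 and 61. The R1881 sites with the best ranks lay at chromosome 16 46432609 to 46432676, with scores of 90.3 and 79.8, at chromosome Y 58823501 to 58823617, with 37.5 and 100.0, and at chromosome 4 49654361 to 49654516, with 35.4 and 94.6, for replicates 1 and 2. The nearest DMSO summits were 788, 3734 and 657 bp away. Of the other R1881 sites picked by rank, 4 lay near centromeres, at chromosome 2 91613844 to 91613870, chromosome 4 49154373 to 49154506, chromosome 16 46429874 to 46429898 and chromosome 20 29812749 to 29812758. The site at chromosome 11 62609223 to 62609230 stood alone, with scores of 6.31 and 100.3 and the nearest DMSO summit 2581499 bp away.

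The DMSO sites with the best ranks lay at chromosome 16 46435372 to 46435413, with scores of 55.5 and 109.9, and chromosome 17 25267775 to 25267805, with 24.1 and 37.8. Further ones lay on chromosome Y at 58974924 to 58974933 and 58977154 to 58977168, on chromosome 2 at 90376246 to 90376400, and on chromosome 7 at 61967430 to 61967431. The rest were at chromosome 17 25265283 to 25265289, chromosome 8 46840484 to 46840577, chromosome 21 10798767 to 10798768 and chromosome 2 90229086 to 90229090. All 10 were in crowded windows, and the nearest R1881 summit was 425 to 3892 bp away for 9 of them and 30710 bp away for the last. The 34 and 38 sites exclusive to the libraries of a treatment compare with 68 sites exclusive to the replicate 1 libraries, 208 to the replicate 2 libraries, 27 to R1881 replicate 1 with DMSO replicate 2, and 127 to R1881 replicate 2 with DMSO replicate 1. Sites of exactly 2 libraries therefore shared treatment in 72 cases, replicate number in 276 and neither in 154, and with lists of equal length these were 64, 151 and 95. At equal length the R1881 pair had 28 sites, the DMSO pair 36, the replicate 1 pair 61 and the replicate 2 pair 90, and the order of the remaining pairs turned, to 56 for R1881 replicate 1 with DMSO replicate 2 and 39 for R1881 replicate 2 with DMSO replicate 1. With only 3 ways to pair 4 libraries, no test of this order can reach 0.05.

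**Figure D3:**
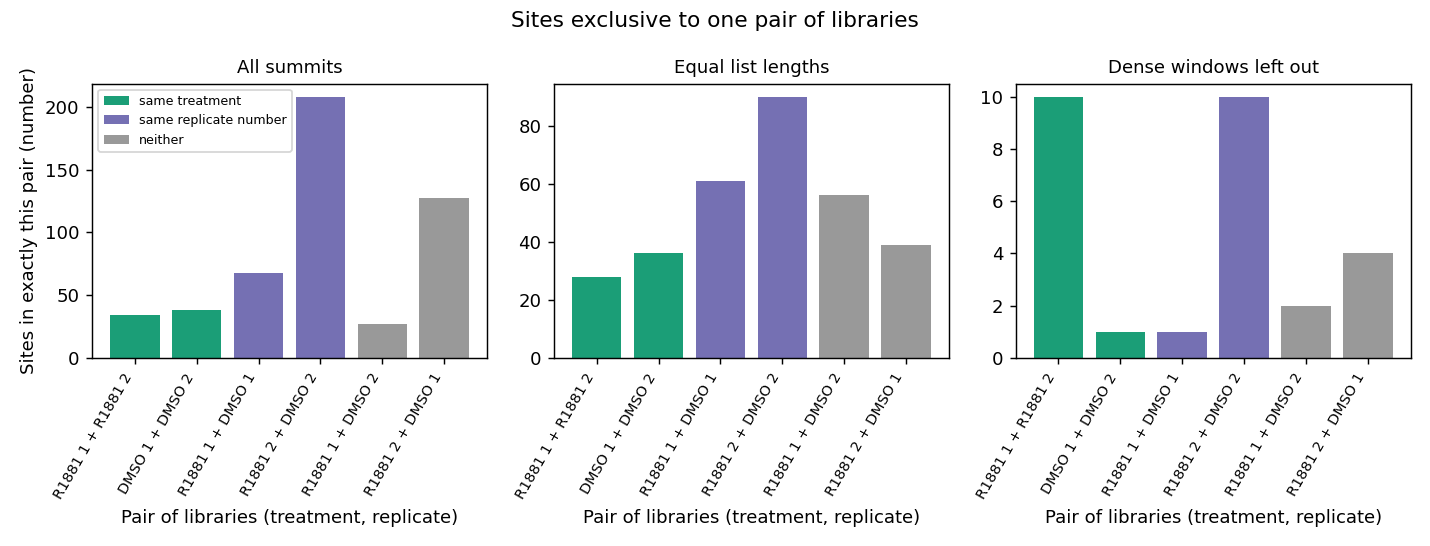
Number of sites found in exactly 1 pair of libraries (y axis) for each of the 6 pairs (x axis), with all summits, with lists of equal length and with crowded windows left out. Bars for pairs of 1 treatment (34 and 38 with all summits) lie below the tallest bar, the replicate 2 pair (208), and with crowded windows left out the R1881 pair and the replicate 2 pair both reach 10.

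With the crowded windows left out, 10 sites belonged to both R1881 libraries alone and 1 to both DMSO libraries alone, while 10 belonged to the replicate 2 pair and 1 to the replicate 1 pair. The other 9 R1881 sites, listed after their values were seen, included chromosome 17 7960299 to 7960359, with scores of 3.15 and 102.2 and the nearest DMSO summit 11006904 bp away, and chromosome 17 18965269 to 18965380, with 5.91 and 63.4 and a DMSO summit 1883 bp away. Sites at chromosome 14 21737706 to 21737918, chromosome 17 26368567 to 26368572 and chromosome 22 46466236 to 46466366 had scores between 8.04 and 12.3 in both R1881 libraries. The rest lay at chromosome 1 47557289, chromosome 4 95679632 and chromosome 17 45973331 and 80054475. The lone DMSO site, also named after its values were seen, lay at chromosome 1 240348283 to 240348317, with scores of 2.27 and 22.9. R1881 replicate 2 had 241 summits in this part of the genome against 56, 58 and 59 in the other libraries.

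Another pair of R1881 sites picked by rank lay on chromosome 11 away from the centromere. The first, at 65190430 to 65190454, had scores of 26.6 and 79.4, and the other, at 65266604 to 65266672, had 8.23 and 79.0. Each belonged to a cluster, described after its values were seen. The cluster from 65190430 to 65197688 held 6 summits of R1881 replicate 1, 2 of R1881 replicate 2 and 3 of DMSO replicate 2, whose nearest summit was 275 bp from the R1881 site. The cluster from 65266604 to 65274469 held 7, 1 and 7 summits of the same libraries, and the nearest DMSO summit was 1354 bp from the R1881 site. DMSO replicate 1 had no summit in either cluster, and the highest scores of DMSO replicate 2 were 8.47 and 11.6. Those of R1881 replicate 1 were 26.6 and 8.93, and scores rank peaks only within 1 list. The summits of both R1881 libraries at the start of each cluster thus had no DMSO summit within 250 bp, while both clusters as a whole did hold DMSO summits.

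**Figure D4:**
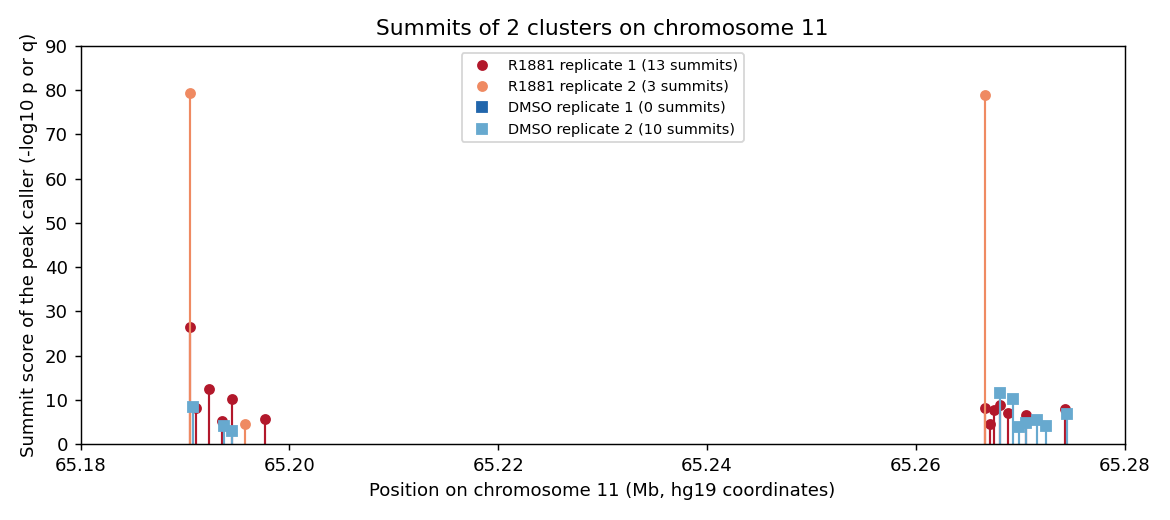
Summits of a pair of clusters on chromosome 11 (x axis, Mb, hg19) with the authors' score (y axis, minus log10 of p or q), with 1 line and point per summit, circles for R1881 and squares for DMSO. R1881 replicate 2 has the highest point of each cluster (79.4 and 79.0), R1881 replicate 1 and DMSO replicate 2 have most of the lower points, and DMSO replicate 1 has none.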

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

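The alternatives for windows and for kinds of pairs were chosen after seeing the data. Over the planned results, 30 alternative values stayed within the spread between replicates or within 1.5 times of the reported count and 20 moved further. That spread, 0.635 in log2 of the summit number, came mostly from the R1881 libraries. Counts with a library or the crowded windows left out change by construction, so the tally does not measure robustness. None of the planned results has a called direction, and the log2 ratio, 0.09 as reported, was −0.02 with all sequences. R1881-only sites were fewer than DMSO-only sites as reported (34 against 38) but more with crowded windows left out or a joining distance of 1000 bp. With crowded windows left out, the log2 ratio of summit number was 1.34, the shared sites were 23 for the R1881 and 14 for the DMSO replicates, and 10, 1 and 8 sites were left in both R1881 libraries alone, both DMSO libraries alone and all 4 libraries, by construction on fewer summits. With a joining distance of 1000 bp, 14 R1881-only and 8 DMSO-only sites were left. With equal list lengths, the DMSO replicates shared 252 sites and all 4 libraries 118, again on fewer summits, and the ratio of numbers is fixed at 1. With all sequences, DMSO-only sites numbered 61 and R1881-only sites 35.

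Leaving out 1 library moved the log2 ratio between −0.68 (without R1881 replicate 2) and 0.59 (without R1881 replicate 1). Sites of the remaining R1881 and no DMSO library ranged from 78 (without DMSO replicate 1) to 612 (without R1881 replicate 1), with 115 without DMSO replicate 2 and 170 without R1881 replicate 2. The DMSO counterpart ranged from 56 (without R1881 replicate 1) to 358 (without DMSO replicate 2), with 216 without R1881 replicate 2 and 240 without DMSO replicate 1. Sites of all remaining libraries ranged from 201 to 362 (without R1881 replicate 1). Membership needs fewer libraries in these counts. Sharing within a treatment has no such value, since it needs both libraries.

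With the replicate block the log2 ratio was −0.048. Deviations of same-numbered libraries, replicate 1 minus 2 in log2 share, correlated at −0.488 over 39 windows, the sign that crossed numbers would give. List lengths were not made equal for this value. R1881 replicate 1 had no summit in 16 of these windows, where its share rests on an added count of 0.5. Sites of exactly 2 libraries shared the labelled number in 276 cases and neither label in 154, and neither pairing gives a call. Sample titles and peak names of all 4 libraries carry the tag G2 for replicate 1 and G3 for replicate 2, which goes with the labelled numbers. Of the results added later, 14 alternative values stayed and 10 moved. Promoter, motif and gene-list results were not run. Read depth is unknown, so what depth limits was not measured.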

Other observations

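All tests in this part were chosen after the results they bear on had been seen. A few further regions had summits of some or all libraries. The mitochondrial genome held 9 summits of DMSO replicate 1, with a highest score of 123, and 1 of R1881 replicate 1, with a score of 14.4, and neither replicate 2 library had one. At the start of chromosome 1, positions 567582 to 568818 held 3 summits of DMSO replicate 1 alone, while the nearby stretch from 724166 to 726964 held 2, 4, 3 and 4 summits of R1881 replicates 1 and 2 and DMSO replicates 1 and 2. The contig gl000220 held 2 and 6 R1881 summits and 1 and 5 DMSO summits.

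Away from crowded windows, 8 sites had summits in all 4 libraries. They included chromosome 14 106110229 to 106110241, with scores of 22.8 and 12.7 in the R1881 libraries and 17.1 and 30.7 in the DMSO libraries, and chromosome 9 72653255 to 72653266, with 37.0, 52.2, 17.3 and 71.8 in the same order. Others lay at chromosome 2 109815980 to 109816130 and 5162768 to 5162879, chromosome 18 50319174 to 50319185 and chromosome 1 224199587 to 224199745. On chromosome 17, the R1881 site at 18965269 had a neighbour at 18967263 to 18967343 with summits of both replicate 2 libraries, with scores of 56.4 for R1881 and 5.69 for DMSO.

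Most summits lay in a few windows in both treatments. Sequence with many genomic copies and few assembled ones, as near centromeres, may collect reads whatever the treatment. Of the 39 windows with at least 20 summits, 56.4% held a summit of all 4 libraries (95% Wilson interval 41.0 to 70.7). More of these windows held all 4 than did not, but the interval also allows a minority. It treats windows of the same 4 libraries as independent, so the percentage does not decide on this explanation. This measure also depends on list length, since 16 of the 39 had no summit of R1881 replicate 1, the shortest list. By treatment, each of the 39 held summits of R1881 replicate 2 and of a DMSO library, so none was limited to either treatment. B-MYB bound there with and without androgen would give the same picture. The input libraries, which might bear on this, were not analysed here, and whether they served as controls in peak calling is not given.

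Regional shares paired libraries that share neither treatment nor replicate number in 25 of 39 windows. This was so in 63.6% of 22 windows with equal list lengths, 60.0% of 35 on chromosomes 1 to 22, X and Y, and 41.9% of 31 with a score of at least 5. With equal list lengths on chromosomes 1 to 22, X and Y it was so in 33.3% of 21, the level of chance without ties. Tied windows counted there as not of this kind, and their number was not recorded. Neither equal lengths nor the choice of chromosomes alone brought the share to that level, and unequal list lengths stay open as an explanation. R1881 replicate 1, the shortest list, had no summit in 16 of the 39 windows and so could not have a high share there. Exchanged labels within one replicate number would also pair libraries that share neither label. Sites of exactly 2 libraries sharing neither label outnumbered those sharing treatment on all sites, 154 against 72, and with equal list lengths, 95 against 64. With crowded windows left out they did not, 6 against 11, so these counts leave exchanged labels open. The peak names of 3 lists carry the treatment of their labels, which goes with the labels as given. An exchange before the peaks were named would not show in the names. An effect of androgen that differs between replicates stays untested.

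More lone sites belonged to both R1881 libraries alone (10) than to both DMSO libraries alone (1), as androgen-dependent binding might give. The longer list of isolated summits of R1881 replicate 2 is a candidate explanation. Among the 56 highest-scoring isolated summits of each library, 4 sites belonged to both R1881 libraries alone and 1 to both DMSO libraries alone, too few to decide, while 5 belonged to the replicate 2 pair, 5 to R1881 replicate 1 with DMSO replicate 2, 1 to the replicate 1 pair and 0 to R1881 replicate 2 with DMSO replicate 1. Sharing between any 2 libraries rather than treatment is another, since 11 lone sites were shared by libraries of the same replicate number, as many as by libraries of the same treatment. These explanations and an effect of androgen cannot be told apart with 2 libraries per treatment and unknown depth.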
